A study of Prunus mongolica with 24 samples.

How the data were processed

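Leaf RNA of wild-type Prunus mongolica seedlings was sequenced in 24 libraries, which the labels place in 8 groups of 3 biological replicates and in a single batch. Prunus mongolica is a desert almond shrub of northern China. The groups were control (CK), GABA (G), alkali-salt (S), cadmium (Cd), alkali-salt with cadmium (SCd), and each of these stresses with GABA (SG, CdG and SCdG). Per the labels, the alkali-salt solution held 10 mmol/L of bicarbonate and carbonate salts (NaHCO3 at 0.81 g/L with Na2CO3 at 0.036 g/L) at pH 8.5 to 8.8, cadmium was given at 0.5 mmol/L (97 mg/L of the hydrated chloride) and GABA at 0.9 mmol/L (92.8 mg/L). Libraries were made from polyadenylated RNA with a strand-marking kit and read as pairs of 150 bases on a NovaSeq X Plus instrument. Treatment length and time of day at harvest are not stated in the sources used here.

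The submitters' processing notes name cutadapt, FastQC 0.10.1, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 1.22.2 and edgeR 3.22.5, with no role, order or genome build. The deposited count matrices hold estimated counts per gene and per transcript, given as whole numbers, and the deposited tables hold FPKM beside the same counts with a description for each gene. The gene and transcript matrices were identical, since each gene had 1 transcript. The matrix held 23798 genes, of which 1646 had 0 counts in every library; the other 22152 were in the annotated table, 22101 with a description and 8233 with none that names a function. In 99.9996% of cells the count equalled the authors' FPKM times the length times 1 constant per library, rounded up, within 1 count plus a relative 1e-04. This relation also holds when FPKM is computed from tallies of reads, so it does not tell such tallies from counts rebuilt from coverage. The values are taken here as estimated counts, although the test had been chosen for counts. The count test was kept because the values are whole numbers, and how well its model holds for such values was not tested. Counts of 4 were 1.83 times as frequent as the mean of 3 and 5, and those of 8 were 1.41 times as frequent as 7 and 9. This looks as if 1 fragment gave about 4 counts. Whether counts were rebuilt from coverage, and with what read length, is not stated, so this was not settled. If 1 fragment gave 4 counts, totals of 52.1 to 68.1 M counts are 13 to 17 M fragments. A rerun on counts divided by 4 was added after the data were seen. Gene names come from the deposited descriptions only, most of them taken from peach (10864) and almond (8433) proteins. Coordinates are those of the deposited table, on sequences numbered 1 to 8, in a build not given in the sources used here. Members of multigene families can share reads, and how the submitters' counting divided these is not stated, so values of near-identical copies are uncertain.

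Counts were analysed with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were kept with filterByExpr at a minimum count of 10, which left 19435 genes. Libraries were scaled by TMM (factors 0.925 to 1.10), and all 24 entered 1 model with a mean per group, so that every comparison shared the estimate of spread. Robust dispersions, the quasi-likelihood F test and Benjamini-Hochberg adjustment over genes were used in each comparison, with a threshold of 0.05. Values per gene are counts scaled to the library total (CPM) as mean ± SD over 3 libraries. Log2 differences are edgeR estimates with its default prior count, and log2 CPM values used a prior count of 2. The SE of a log2 difference is its absolute size divided by the square root of its F statistic. A gene is called separated when every library of 1 group lies above every library of the other, which chance gives for 10% of genes with 3 against 3. The p-values measure only the spread between these biological replicates.

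Gene lists, 35 in all, were defined by patterns in the gene descriptions. They covered pathways, the daily clock, and markers of other tissues or cell types. The jasmonate pattern also caught the word rectifying, and the cell division pattern the phrase cyclin-dependent. Each list was tested with camera on voom values with a preset correlation of 0.01, two-sided and adjusted over 35 lists and 9 pairwise comparisons together. Beside it stand the number of members past the gene test over all genes and adjusted over the list alone. The tests, lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined, except those said to be chosen later. That rule took, per pairwise comparison, the 6 largest positive and 6 largest negative log2 differences among separated genes past the test with at least 1 CPM in either group and a description naming a function; the 3 members with the smallest p of each list called by camera; and the tested members of the GABA metabolism list and of the metallothionein, phytochelatin synthase and nicotianamine synthase families. Genes named for interactions, for averages over pairs, for counts of 5 or fewer, and 3 clock genes in SCdG against CK were chosen after their values were seen.

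Alternatives were DESeq2 1.42.0, RLE scaling, no count filter, only the compared groups in the model, a replicate block, a log2 difference of at least 1, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Chosen after the data were seen were 3 comparisons of GABA groups with CK, 5 averages over pairs of groups that differ in 1 treatment, counts divided by 4, fry, camera with each library left out, exact permutation of list means, a clock score as covariate, and one-sided Fisher tests over the pathway names of the deposited table. The clock score is the first principal component of the 19 clock genes over the 24 libraries. Correlations across libraries used 100000 permutations. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures.

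The test was run first on simulated counts drawn from the CK means and the real library sizes (18787 genes tested). It found 41 of 100 genes changed by 1 on the log2 scale and 82 of 100 changed by 2, with 8 false calls among 131, and no call between unchanged groups. In simulated counts for SG and S, camera found a list shifted by 0.4 on the log2 scale and no other list. Genes were drawn independently of each other there, so this does not test camera where members of a list are correlated.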

Results

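Leaf RNA was measured in 24 libraries of wild-type Prunus mongolica seedlings, 3 biological replicates in each of 8 groups. The groups combine a bicarbonate alkali-salt solution, cadmium, and GABA (gamma-aminobutyric acid, a non-protein amino acid that plants make from glutamate). The series asks how GABA alters the response of this shrub to alkali-salt and cadmium given together. Totals ran from 52.1 to 68.1 M deposited counts per library, or 13 to 17 M if 1 fragment gave 4 counts. Totals below 56 M occurred in 4 libraries, with 52.7 M in CK replicate 2, 52.1 M in Cd replicate 2, 52.2 M in SG replicate 3 and 55.3 M in SCdG replicate 2. The median correlation of log2 CPM across genes was 0.950 within groups and 0.945 between groups, and replicates varied by 41.4% (biological coefficient of variation). Unless said otherwise, values are CPM as mean ± SD with n = 3 per group, and log2 differences are edgeR estimates ± SE.

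**Figure D1:**
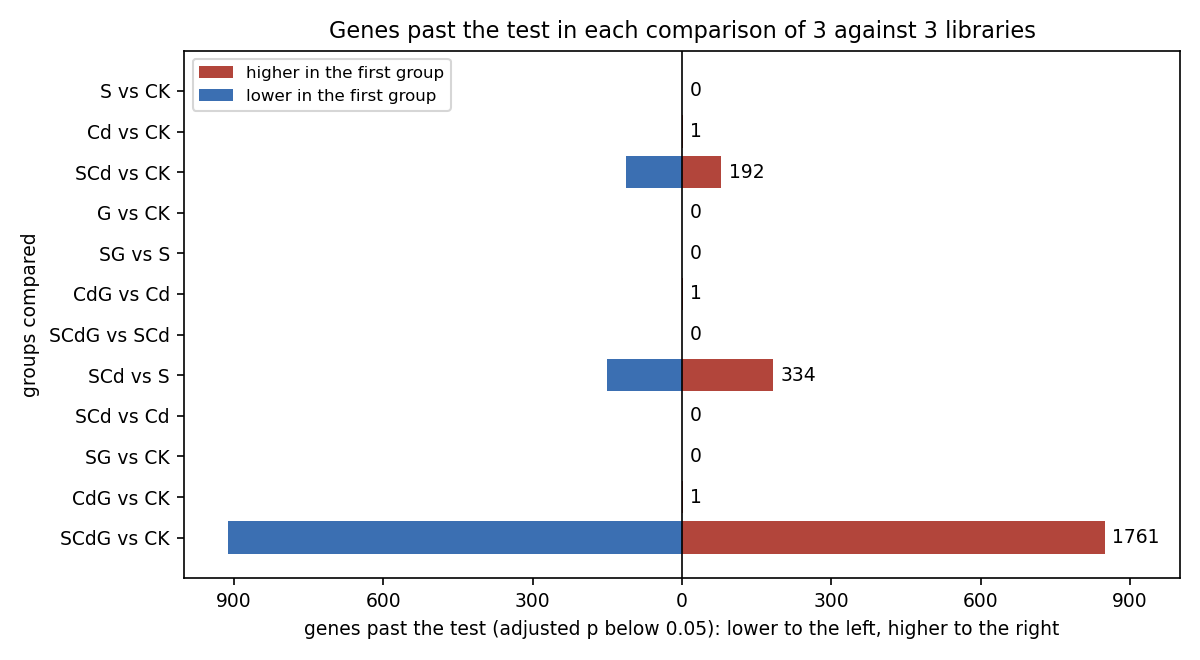
Bars give the number of genes past the edgeR test (adjusted p threshold 0.05, 19435 genes tested) that were higher or lower in each of 12 pairwise comparisons. SCdG against CK had 849 higher and 912 lower genes, SCd against S 183 and 151, SCd against CK 79 and 113, and the other comparisons 0 or 1 in all.

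The comparison of SCd with CK asks what the combined stress did to leaf expression. Beta galactosidase 1 (Pmo03G004270; sequence 3, 3366121 to 3372442), of a family that trims galactose from cell wall polymers, rose from 203 ± 42.3 to 805 ± 164 CPM (log2 difference 1.99 ± 0.42). Transcripts described as codeine O-demethylase (Pmo04G021110), an oxygenase family member, rose from 6.82 ± 4.74 to 45.8 ± 10.2 CPM, and the zinc finger factor CONSTANS-LIKE 6 (Pmo03G026210) from 4.05 ± 2.44 to 16.0 ± 3.76 CPM. IAA1 (Pmo07G021340; sequence 7, 22437916 to 22442086), a repressor of auxin responses, fell from 30.3 ± 27.4 to 4.14 ± 2.68 CPM (log2 difference -2.87 ± 0.61). APS reductase 3 (Pmo04G001590; sequence 4, 890202 to 893465), which reduces activated sulfate on the way to cysteine, fell from 407 ± 182 to 107 ± 53.4 CPM (-1.93 ± 0.42). The trihelix factor ASIL2 (Pmo02G003160) fell from 33.6 ± 16.0 to 7.91 ± 1.2 CPM.

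Other genes higher in SCd by the naming rule were tobamovirus multiplication protein 1 (Pmo03G015820, log2 difference 1.90 ± 0.38), an IRK-interacting protein (Pmo06G005410, 1.82 ± 0.41) and the cation channel glutamate receptor 2.8 (Pmo01G035280, 1.80 ± 0.40). Lower were a DOG1-like 4 gene (Pmo06G024410, -2.73 ± 0.45), the N-acetyltransferase HLS1 (Pmo06G004420, -2.27 ± 0.48) and a BTB/POZ protein (Pmo08G022090, -2.16 ± 0.40). In each of these 12 genes every SCd library lay on the same side of every CK library, which the naming rule required and so is no further evidence. Their edgeR adjusted p ran from 0.00767 to 0.0376. Heat shock and chaperone genes lay higher as a list (59 of 91 with a positive difference, list mean 3.45 ± 0.10 in SCd and 3.03 ± 0.18 log2 CPM in CK, camera adjusted p = 0.00936). This call was lost with an estimated correlation (adjusted p = 0.842), and no member passed the gene test over all genes or adjusted over the list alone. Its members with the smallest p were dnaJ 11 (Pmo01G032130, 713 ± 89.2 against 157 ± 171 CPM, edgeR adjusted p = 0.0746), dnaJ 8 (Pmo03G008680, 282 ± 113 against 91.1 ± 55.2, 0.0721) and the heat stress factor A-7a (Pmo08G020310, log2 difference 1.36 ± 0.41, 0.107). The list kept its call in 4 of 6 fits with a library left out and lost it without CK replicate 1 or SCd replicate 2, with camera adjusted p up to 0.0703. CK replicate 2 held 355 CPM of dnaJ 11 and the other CK libraries 57.0 and 59.0; without it the log2 difference went from 2.18 to 3.62 and passed (edgeR adjusted p = 0.000201).

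In all, edgeR called 192 of 19435 genes in SCd against CK (79 higher, 113 lower, 114 of them at least 2-fold), and 2752 had an unadjusted p under 0.05. Independent genes would give 971.75 by chance, but other splits of these 6 libraries gave up to 2334. Beta galactosidase 1, IAA1 and the other named genes all kept their calls without CK replicate 2, when 1355 genes passed. Of these 12 named genes, 1 passed without CK replicate 1, 0 without CK replicate 3, 3 without SCd replicate 1, 1 without SCd replicate 2 and 0 without SCd replicate 3. IAA1 had -1.83 without CK replicate 1 (edgeR adjusted p = 0.201). The matching totals were 13, 2, 38, 7 and 6 genes, and with only the 6 compared libraries in the model edgeR called 0 (DESeq2 with all libraries 927, limma 315). Which direction held more genes depended on the setting: limma had 196 higher and 119 lower on log2(FPKM + 1) and 197 and 116 on log2(FPKM + 0.1), and edgeR 785 and 570 without CK replicate 2 and 139 and 135 with a replicate block. The clock score, a summary of 19 clock genes, averaged 2.36 ± 1.28 in SCd and -3.73 ± 2.50 in CK, with CK replicate 2 at -0.853.

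The comparison of S with CK asks what alkali-salt did by itself. Phenylpropanoid and lignin genes lay higher in S (45 of 70 with a positive difference, list mean 2.66 ± 0.14 against 2.25 ± 0.14 log2 CPM). Among them were a shikimate O-hydroxycinnamoyltransferase (Pmo03G008710, an enzyme of lignin synthesis) at 94.9 ± 10.1 against 38.2 ± 5.09 CPM and 4-coumarate-CoA ligase-like 9 (Pmo01G020250) at 6.34 ± 2.2 against 2.21 ± 1.21 CPM. Jasmonate genes lay higher too (27 of 35, median log2 difference 0.42), with the repressor TIFY 6B-like (Pmo01G028970) at 126 ± 19.4 against 68.7 ± 12.1 CPM and allene oxide cyclase (Pmo03G021280) at 57.5 ± 47.5 against 14.4 ± 7.46 CPM. Cytosolic ribosome genes were shifted by a median of only 0.08 (68 of 97 positive), such as RPL34-1-like (Pmo01G024080) at 26.4 ± 4.95 against 19.2 ± 3.34 CPM. All 5 of these genes were separated, and none passed the gene test (smallest edgeR adjusted p 0.574). Allene oxide cyclase was at 112 CPM in S replicate 2 and at 35.3 and 25.0 CPM in the other S libraries, and its log2 difference of 1.99 became 1.06 without that library. Without S replicate 3 that of RPL34-1-like went from 0.46 to 0.29.

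Camera gave adjusted p = 0.0303 for phenylpropanoid, 0.0424 for jasmonate and 0.029 for ribosome genes, and 0.861, 0.861 and 0.904 with an estimated correlation. Adjusted over the list alone, 1 phenylpropanoid gene and no jasmonate or ribosome gene passed. The phenylpropanoid call was lost without CK replicate 2 or 3 or S replicate 1 or 2 (adjusted p up to 0.184). The jasmonate call was lost without CK replicate 2 or 3 or S replicate 2 (up to 0.614), and the ribosome call without CK replicate 1 or S replicate 2 or 3 (up to 0.870). No single gene passed in S against CK with edgeR (smallest adjusted p 0.0829). At an unadjusted p under 0.05 there were 1383 genes, and other splits of these 6 libraries gave up to 1756. DESeq2 called 55, and limma on log2(FPKM + 1) called 2. Without CK replicate 2 edgeR called 51 genes and without CK replicate 1 it called 1.

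The comparison of Cd with CK asks what cadmium did by itself. MCA2 (Pmo02G021840; sequence 2, 26382569 to 26384415), a homologue of a calcium-permeable mechanosensitive protein, was at 0.365 ± 0.242 CPM in Cd and at 0 in all 3 CK libraries. It was the single gene past the test (edgeR adjusted p = 0.0426) and was chosen for naming after its value was seen. Phenylpropanoid genes lay higher in Cd (48 of 70 positive), with laccase-4-like (Pmo02G021000) at 2.18 ± 2.57 against 0.494 ± 0.0541 CPM and phenylalanine ammonia-lyase 2 (Pmo02G017990), which opens this pathway, at 77.1 ± 21.5 against 40.5 ± 10.7 CPM. Cell wall loosening genes lay higher as well (60 of 88 positive), such as xyloglucan endotransglucosylase 23 (Pmo01G007250) at 2.16 ± 1.38 against 0.219 ± 0.124 CPM and expansin-A4 (Pmo06G022480) at 228 ± 120 against 85.0 ± 43.3 CPM. Of 19 clock genes, 13 had a positive difference, among them the evening gene ELF4-LIKE 3 (Pmo07G018300) with 1.10 ± 0.36, while ELF4-LIKE 4 (Pmo03G003590) had -0.49 ± 0.14. Laccase-4-like was at 5.14 CPM in Cd replicate 2 and at 0.559 and 0.851 CPM in the other Cd libraries, and its log2 difference of 2.14 became 0.51 without that library. Without Cd replicate 3 that of expansin-A4 went from 1.42 to 0.93, and without CK replicate 2 ELF4-LIKE 3 had 1.77 and passed (edgeR adjusted p = 0.0114).

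Camera gave adjusted p = 0.0244 for phenylpropanoid, 0.0455 for cell wall loosening and 0.0483 for clock genes, each 0.861 with an estimated correlation, and adjusted over the list alone only 1 clock gene passed, as lower. The phenylpropanoid call was lost without CK replicate 2 or 3 or Cd replicate 1 (adjusted p up to 0.277), and the wall loosening call without CK replicate 2 or 3 or Cd replicate 2 (up to 0.309). The clock call was lost without CK replicate 1 or 3 or Cd replicate 2 or 3 (up to 0.179). In Cd against CK 1267 genes had an unadjusted p under 0.05, and other splits of these 6 libraries gave up to 1916. MCA2 kept its call without CK replicate 2 (when 202 genes passed) or Cd replicate 3 (1 gene). It lost it without CK replicate 1 (edgeR adjusted p = 0.376), CK replicate 3 (0.202), Cd replicate 1 (0.0835) or Cd replicate 2 (0.103), and 0 genes passed in those fits; DESeq2 called 45 genes and limma 0, as did edgeR with a replicate block, counts divided by 4 or only the compared groups.

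SCd against S asks what cadmium added under alkali-salt. MIEL1 (Pmo07G011440; sequence 7, 16325638 to 16328137), a ubiquitin ligase, rose from 8.66 ± 1.86 to 116 ± 26.3 CPM (log2 difference 3.74 ± 0.65), and beta galactosidase 1 from 123 ± 27 to 805 ± 164 CPM (2.71 ± 0.43). A further beta-galactosidase (Pmo07G018960) rose from 30.6 ± 16.3 to 367 ± 48.5 CPM, and SNF1-related kinase subunit gamma 1 (Pmo05G013380), part of a kinase complex that senses energy status, from 10.5 ± 0.342 to 80 ± 20.9 CPM. Pectinesterase (Pmo01G028890), a cell wall enzyme, fell from 36.6 ± 30.9 to 5.73 ± 2.95 CPM (-2.67 ± 0.60). Patatin-like 2 (Pmo01G038710), a lipid hydrolase, fell from 4.06 ± 1.77 to 0.279 ± 0.145 CPM, and early light-induced protein 1 (Pmo01G001820) stood at 0 in SCd and 1.18 ± 0.81 CPM in S. The other 5 genes of the naming rule were crocetin glucosyltransferase (Pmo01G014100, 3.76 ± 0.86) and GDAP2 (Pmo01G031540, 3.21 ± 0.62), which rose, and a WAT1-related protein (Pmo01G043800, 3.85 ± 0.103 to 0.0612 ± 0.106 CPM), JINGUBANG (Pmo01G034070, -2.93 ± 0.55) and myb-related 308 (Pmo03G003560, -2.80 ± 0.71), which fell.

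As lists, jasmonate genes lay lower in SCd than in S (27 of 35 negative, median log2 difference -0.50), as did guard cell and epidermis genes (30 of 46), such as the wax enzyme 3-ketoacyl-CoA synthase 1 (Pmo02G016670) at 18.9 ± 0.516 against 39.2 ± 3.58 CPM. Ribosome genes lay lower by a median of 0.10 (69 of 97 negative), and photosystem and antenna genes higher (39 of 48 positive, median 0.19), such as the antenna gene Lhca6 (Pmo05G017370) at 2626 ± 683 against 1024 ± 170 CPM. By camera, adjusted p was 0.028, 0.029, 0.0237 and 0.0405 in this order, 0.861, 0.861, 0.897 and 0.921 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The jasmonate call was lost without S replicate 2 (0.368), the guard cell call without S replicate 1 or 3 or SCd replicate 1 or 3 (up to 0.335), the ribosome call without S replicate 3 or SCd replicate 3 (up to 0.357), and the photosystem call without S replicate 2 or 3 or SCd replicate 3 (up to 0.803). EdgeR called 334 genes (183 higher, 151 lower, 190 at least 2-fold), while limma had 159 higher and 196 lower on log2(FPKM + 1) and 149 and 193 on log2(FPKM + 0.1), and 2704 had an unadjusted p under 0.05. All 12 genes were separated, as the naming rule required (edgeR adjusted p 0.00643 to 0.0492), and beta galactosidase 1 kept its call in all 14 other settings. MIEL1 lost its call only without S replicate 3 (0.0639). The WAT1-related gene was seen in SCd replicate 2 alone of its group, so its log2 difference of -5.92 ± 1.4 became -10.92 without that library and -1.71 in limma on log2(FPKM + 1). Pectinesterase had -1.75 without S replicate 2 (edgeR adjusted p = 0.16). The clock score was -1.57 ± 0.90 in S and 2.36 ± 1.28 in SCd. The total fell to 98, 105 and 54 genes without S replicate 1, 2 or 3, of which 47, 42 and 15 were higher, and to 52, 82 and 85 without SCd replicate 1, 2 or 3.

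SCd against Cd asks what alkali-salt added under cadmium. Heat shock and chaperone genes lay higher in SCd (64 of 91 positive, list mean 3.45 ± 0.10 against 3.14 ± 0.09 log2 CPM), among them an HSP20-like chaperone (Pmo04G011070) at 2.27 ± 1.24 against 0.267 ± 0.193 CPM and mitochondrial HSP90-6 (Pmo03G018090) at 13.1 ± 1.59 against 7.06 ± 1.48 CPM. Camera gave adjusted p = 0.00473 (0.842 with an estimated correlation, and 0.0703 without SCd replicate 2), with 0 members past over all genes or adjusted over the list alone. With edgeR 0 genes passed (smallest adjusted p 0.0575; 1763 at an unadjusted p under 0.05; 1 without Cd replicate 1 and 1 without Cd replicate 3), and DESeq2 called 203, limma 6 and edgeR with RLE scaling 7.

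The interaction of alkali-salt and cadmium asks whether the pair departed from the sum of the single stresses on the log2 scale. A gene whose description is shortened to 1-aminocyclopropane-1-carboxylate (Pmo01G015990; sequence 1, 17259754 to 17262271), so that its enzyme cannot be named, had 124 ± 13 CPM in CK, 66.7 ± 1.81 in S, 57.0 ± 3.33 in Cd and 111 ± 32.1 in SCd. Nucleoredoxin 3 (Pmo01G040260), a thiol oxidoreductase, had 37.1 ± 4.37, 25.2 ± 4.17, 27.4 ± 4.77 and 50.6 ± 6.95 CPM. Both passed (log2 interactions 1.86 ± 0.27 and 1.44 ± 0.22, edgeR adjusted p = 0.0215 each), were the only genes that did, and were named after their values were seen. Phenylpropanoid (50 of 70 negative) and cell wall loosening genes (61 of 88 negative) had interactions below 0 as lists (camera adjusted p = 0.0091 and 0.00463, and 0.513 and 0.685 with an estimated correlation). When adjusted over the list alone, 2 phenylpropanoid genes and no wall loosening gene passed. Both gene calls ended without CK replicate 1 or 2, Cd replicate 1 or 2, S replicate 2, or SCd replicate 1 or 3, when 0 genes passed; log2 interactions there were 1.64 to 1.86 and 1.30 to 1.51 (edgeR adjusted p 0.0574 to 0.108). Without S replicate 1 a single gene passed, without S replicate 3 there were 4 and without CK replicate 3, Cd replicate 3 or SCd replicate 2 there were 3 each. With only the compared groups in the model edgeR called 0 genes. A replicate block gave 6, both named genes among them, DESeq2 called 113 and limma on log2(FPKM + 1) 3.

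The comparison of G with CK asks what GABA did in unstressed leaves. Chlorophyll biosynthesis genes lay higher in G (20 of 21 positive, median log2 difference 0.33), such as glutamyl-tRNA reductase 1 (Pmo01G047290), the first committed step, at 804 ± 215 against 533 ± 140 CPM. Phenylpropanoid genes lay higher (48 of 70 positive), with phenylalanine ammonia-lyase 1 (Pmo06G020580) at 339 ± 75.2 against 135 ± 37.4 CPM and 4-coumarate-CoA ligase-like 9 at 7.02 ± 0.989 against 2.21 ± 1.21 CPM. So did cell wall loosening genes (60 of 88 positive), such as expansin-A1 (Pmo05G017380) at 19 ± 11.6 against 6.72 ± 4.06 CPM. Without G replicate 2 the log2 difference of expansin-A1 went from 1.5 to 0.93, and without CK replicate 3 that of glutamyl-tRNA reductase 1 from 0.59 to 0.39. The camera adjusted p was 0.0331, 0.0405 and 0.0234, each 0.861 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. The chlorophyll call was lost without CK replicate 3 or G replicate 2 or 3 (up to 0.502), the phenylpropanoid call without CK replicate 2 or 3 or G replicate 1 or 3 (up to 0.278), and the wall loosening call without CK replicate 2 or 3 or G replicate 3 (up to 0.178). With edgeR 0 genes passed (smallest adjusted p 0.177, and 6 genes without CK replicate 2), DESeq2 called 38 and limma 0. At an unadjusted p under 0.05 there were 1458 genes, and other splits of these 6 libraries gave up to 2360. The clock score was -2.25 ± 2.04 in G and -3.73 ± 2.50 in CK.

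SG against S asks what GABA did under alkali-salt. Photosystem and antenna genes lay higher in SG (45 of 48 positive, list mean 8.91 ± 0.16 against 8.44 ± 0.10 log2 CPM), with Lhca6 at 2861 ± 477 against 1024 ± 170 CPM, CP24 (Pmo01G048710) at 1746 ± 273 against 924 ± 96.6 CPM and an LHCII type 1 gene (Pmo04G006710) at 5325 ± 464 against 3261 ± 88.4 CPM. Chlorophyll biosynthesis genes lay higher as well (19 of 21, list mean 7.12 ± 0.13 against 6.66 ± 0.09). Among them protochlorophyllide reductase (Pmo04G016390; sequence 4, 11249656 to 11251423), the light-driven step, had 558 ± 192 against 152 ± 12.0 CPM. Magnesium-protoporphyrin IX methyltransferase (Pmo05G012520) had 125 ± 11.7 against 65.8 ± 8.22 CPM, and chlorophyllide a oxygenase (Pmo01G043450) 576 ± 62.6 against 451 ± 24.4 CPM. Carbon fixation genes (10 of 12), with phosphoribulokinase (Pmo05G002200) at 3547 ± 395 against 2813 ± 221 CPM, and scavenging genes (26 of 33), with dehydroascorbate reductase 2 (Pmo02G019260) at 118 ± 13.4 against 91.6 ± 4.07 CPM, lay higher. Jasmonate genes (28 of 35 negative), with TIFY 9 (Pmo01G019090) at 4.01 ± 0.761 against 6.78 ± 0.0909 CPM, and WRKY factors (28 of 46 negative), with WRKY7 (Pmo06G020170) at 15.1 ± 2.17 against 27.6 ± 1.33 CPM, lay lower.

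Camera adjusted p was 8.05e-13 for photosystem, 3e-06 for chlorophyll, 0.0234 for carbon fixation, 0.0364 for scavenging, 0.0207 for jasmonate and 0.0424 for WRKY genes, and 0.842 to 0.861 for all 6 with an estimated correlation. Adjusted over the list alone, 2 chlorophyll genes and none of the other lists passed. The photosystem and chlorophyll calls held in all 6 fits with a library left out. The others were lost without S replicate 3 (carbon fixation 0.161, scavenging 0.134), S replicate 2 (jasmonate 0.403, WRKY 0.256), SG replicate 3 (carbon fixation, scavenging and WRKY) or SG replicate 2 (scavenging and WRKY). With edgeR 0 genes passed (smallest adjusted p 0.1; 1747 at an unadjusted p under 0.05; 1 without SG replicate 1), DESeq2 called 192 and limma 0, and edgeR called 3 with a replicate block and 2 with only the compared groups in the model. The clock score was 1.51 ± 0.83 in SG and -1.57 ± 0.90 in S.

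The interaction of GABA with alkali-salt compares this response with that of G against CK. MIEL1 had 22.7 ± 14.6 CPM in CK, 5.43 ± 2.91 in G, 8.66 ± 1.86 in S and 66.3 ± 59.6 in SG (log2 interaction 5.00 ± 0.88), and beta galactosidase 1 had 203 ± 42.3, 94.6 ± 36.9, 123 ± 27 and 636 ± 541 CPM (3.47 ± 0.59). Positive interactions also passed for the metal-binding domain protein HIPP28 (Pmo04G005420, 3.81 ± 0.68), ABHD18 (Pmo07G006730, 3.25 ± 0.54), bHLH110 (Pmo01G033110, 2.03 ± 0.37), trehalose-phosphate synthase 6 (Pmo01G029290, 1.82 ± 0.33) and 3 genes without a functional name (Pmo03G004260, 2.70 ± 0.47; Pmo04G003970, 2.60 ± 0.40; Pmo01G002590, 2.11 ± 0.39). Negative ones passed for the receptor kinase HSL1 (Pmo04G004740, -0.89 ± 0.16) and a protein of unknown function (Pmo01G032440, -1.46 ± 0.25). These 11 genes had the same edgeR adjusted p = 0.0498, just within the threshold, and were named after their values were seen. As lists, photosystem genes had positive interactions (47 of 48), and phenylpropanoid, jasmonate and wall loosening genes negative ones (48 of 70, 28 of 35 and 59 of 88). Camera adjusted p was 5.19e-07, 0.0143, 0.00203 and 0.0221, and 0.754, 0.513, 0.667 and 0.754 with an estimated correlation; adjusted over the list alone 5 jasmonate genes passed and none of the other 3 lists.

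Of these 11 genes 11 kept the call without CK replicate 3 (when 64 genes passed), 10 without CK replicate 1 (20 genes), 8 without SG replicate 3 (13 genes), 6 without SG replicate 1 (12 genes) and 1 without CK replicate 2 (1 gene). None kept it without any G library, any S library or SG replicate 2, when 0 genes passed. Without a G or S library the log2 interactions stayed near their size, at 4.73 to 5.52 for MIEL1 and 3.2 to 3.79 for beta galactosidase 1, and edgeR adjusted p of the 11 genes ran from 0.0522 to 0.146. SG replicate 2 stood apart for beta galactosidase 1 (1257 CPM, with 273 and 378 in the other SG libraries) and MIEL1 (135 CPM, with 33.8 and 30.1). Without it their log2 interactions were 2.50 and 3.95 (edgeR adjusted p = 0.0936 and 0.132). In this interaction 1826 genes had an unadjusted p under 0.05, and DESeq2 called 241 and limma on log2(FPKM + 1) 0. With a replicate block edgeR called 6 genes, 5 of them among the 11 and neither MIEL1 nor beta galactosidase 1, and with only the 4 compared groups in the model it called 0.

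**Figure D2:**
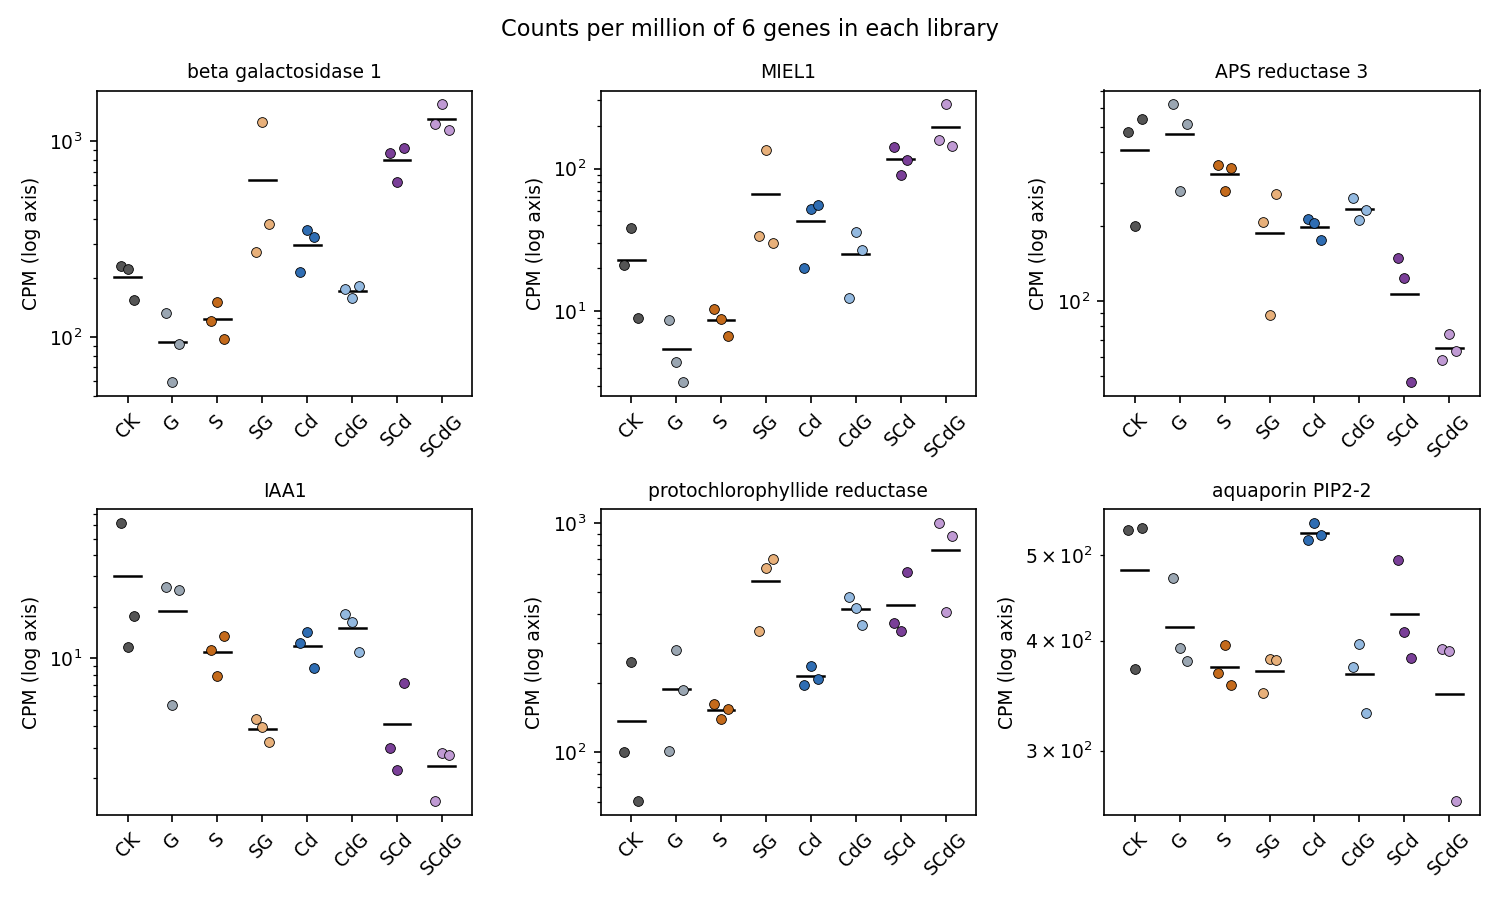
CPM on a log axis in each of the 24 libraries for beta galactosidase 1, MIEL1, APS reductase 3, IAA1, protochlorophyllide reductase and aquaporin PIP2-2; points are libraries and lines are means of 3. MIEL1 averages 116 CPM in SCd and 8.66 CPM in S, and IAA1 4.14 CPM in SCd and 30.3 CPM in CK.

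CdG against Cd asks what GABA did under cadmium. The 1-aminocyclopropane-1-carboxylate gene Pmo01G015990 rose from 57.0 ± 3.33 to 156 ± 19.2 CPM (log2 difference 1.45 ± 0.19). It was the single gene past the test (edgeR adjusted p = 0.00887). Chlorophyll biosynthesis genes lay higher in CdG (21 of 21 positive, list mean 7.09 ± 0.18 against 6.74 ± 0.05 log2 CPM), such as the magnesium-protoporphyrin ester cyclase (Pmo07G002080) at 1436 ± 293 against 899 ± 104 CPM and glutamate-1-semialdehyde aminomutase (Pmo05G012880) at 152 ± 17.6 against 107 ± 17.8 CPM, and photosystem genes did too (39 of 48). Aquaporins, the water channels, lay lower (14 of 15 negative, list mean 2.95 ± 0.10 against 3.63 ± 0.18), with PIP2-2 (Pmo06G008840) at 367 ± 33.0 against 531 ± 12.5 CPM and TIP1-1 (Pmo07G011430) at 284 ± 12.9 against 494 ± 113 CPM. Markers of secondary wall, a list kept to see stem or xylem tissue, lay lower (8 of 10), with xylem cysteine proteinase 1 (Pmo08G015640) at 33.0 ± 18.9 against 65.1 ± 15.4 CPM (log2 difference -0.98, and -1.55 without CdG replicate 2).

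Camera adjusted p was 1.47e-05 for chlorophyll, 0.0331 for photosystem, 0.0019 for aquaporin and 0.00802 for secondary wall genes, and 0.861, 0.910, 0.842 and 0.861 with an estimated correlation. When adjusted over the list alone 1 aquaporin passed. The chlorophyll and aquaporin calls held in all 6 fits with a library left out, the secondary wall call was lost without Cd replicate 1 (0.0541), and the photosystem call without Cd replicate 1 or CdG replicate 1 or 2 (up to 0.841). In CdG against Cd 1328 genes had an unadjusted p under 0.05, and DESeq2 called 66, limma 1 and edgeR with only the compared groups 0. Pmo01G015990 kept its call without CdG replicate 1 (edgeR adjusted p = 0.0412, 1 gene) or CdG replicate 3 (0.00824, 2 genes). It missed it without CdG replicate 2 (0.0673), Cd replicate 1 (0.0646), Cd replicate 2 (0.0954) or Cd replicate 3 (0.0787), when 0 genes passed. The clock score was 0.03 ± 1.03 in CdG and -1.18 ± 0.46 in Cd.

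The interaction of GABA with cadmium also passed for Pmo01G015990, at 124 ± 13 CPM in CK, 83.4 ± 8.82 in G, 57.0 ± 3.33 in Cd and 156 ± 19.2 in CdG (log2 interaction 2.03 ± 0.27, edgeR adjusted p = 0.00914; 0.0501 without Cd replicate 1, when 0 genes passed). It was the single gene that passed, among 1007 at an unadjusted p under 0.05, and DESeq2 called 33, limma 1 and edgeR with only the compared groups 2. Phenylpropanoid (50 of 70 negative), wall loosening (65 of 88), aquaporin (13 of 15) and secondary wall genes (10 of 10) had interactions below 0. By camera, adjusted p was 0.0105, 0.000291, 0.0275 and 0.0275, and 0.513, 0.513, 0.513 and 0.754 with an estimated correlation; no member passed over all genes or adjusted over the list alone.

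SCdG against SCd asks the question of the series, what GABA did under the combined stress. Cytosolic ribosome genes lay higher in SCdG (93 of 97 positive, list mean 4.68 ± 0.13 against 4.39 ± 0.09 log2 CPM), such as RPS2-4 (Pmo02G006700) at 81.2 ± 12.2 against 52.7 ± 1.32 CPM, RPL30 (Pmo01G008000) at 24.4 ± 4.17 against 16.3 ± 2.46 CPM and RPL13a-4 (Pmo01G000590) at 81.5 ± 12.4 against 58.3 ± 5.60 CPM. Photosystem genes (44 of 48), with the repair protein PSB27-H1 (Pmo03G020930) at 207 ± 84.0 against 112 ± 49.6 CPM, and chlorophyll biosynthesis genes (19 of 21) lay higher. Among the latter were glutamate-1-semialdehyde aminomutase at 171 ± 37.9 against 106 ± 15.5 CPM and coproporphyrinogen-III oxidase (Pmo03G016480) at 57.4 ± 17.0 against 37.0 ± 8.91 CPM. Wall loosening genes lay higher (61 of 88), with another expansin-A4 (Pmo06G003480) at 87.1 ± 61.4 against 23.5 ± 12.9 CPM. Clock genes lay lower (16 of 19 negative), with the morning factors LHY (Pmo02G016990) at 1219 ± 365 against 2046 ± 490 CPM, REVEILLE 1 (Pmo03G001330) at 347 ± 56.8 against 524 ± 96.7 CPM and REVEILLE 8 (Pmo06G021200) at a log2 difference of -0.53 ± 0.18. SCdG replicate 2 stood apart from replicates 1 and 3 (first principal component over all genes 8.37 against 83.1 and 71.7). It lay near the SCd mean for PSB27-H1 (121 CPM), coproporphyrinogen-III oxidase (37.8 CPM) and expansin-A4 (19.6 CPM), which were above it in the other 2 libraries. Without SCdG replicate 1 the log2 difference of PSB27-H1 went from 0.88 to 0.57.

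Camera adjusted p was 1.93e-26 for ribosome, 1.47e-05 for photosystem, 0.00028 for chlorophyll, 0.0364 for wall loosening and 0.00198 for clock genes, and 0.842 for ribosome and 0.861 for the other 4 with an estimated correlation. Adjusted over the list alone, 13 ribosome genes passed as higher, 1 clock gene as lower and none of the other lists. The ribosome, photosystem, chlorophyll and clock calls held in all 6 fits with a library left out, and the wall loosening call was lost without SCd replicate 1 or 2 or SCdG replicate 1 or 3 (up to 0.387). With edgeR 0 single genes passed (smallest adjusted p 0.155, and 1 gene without SCdG replicate 1), DESeq2 called 69 and limma 0. At an unadjusted p under 0.05 there were 1693 genes, and other splits of these 6 libraries gave up to 3870. The clock score was 4.82 ± 1.43 in SCdG and 2.36 ± 1.28 in SCd.

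In the interaction of GABA with the combined stress, photosystem (45 of 48) and ribosome genes (84 of 97) had positive differences, and phenylpropanoid (48 of 70) and clock genes (13 of 19) negative ones. The camera adjusted p was 0.000636, 2.84e-16, 0.0246 and 0.0296, and 0.799, 0.513, 0.513 and 0.667 with an estimated correlation, and no member passed adjusted over the list alone. With edgeR 0 genes passed (smallest adjusted p 0.251; 1048 at an unadjusted p under 0.05; 5 without CK replicate 2 and 1 without SCdG replicate 1), DESeq2 called 17 and limma 0.

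**Figure D3:**
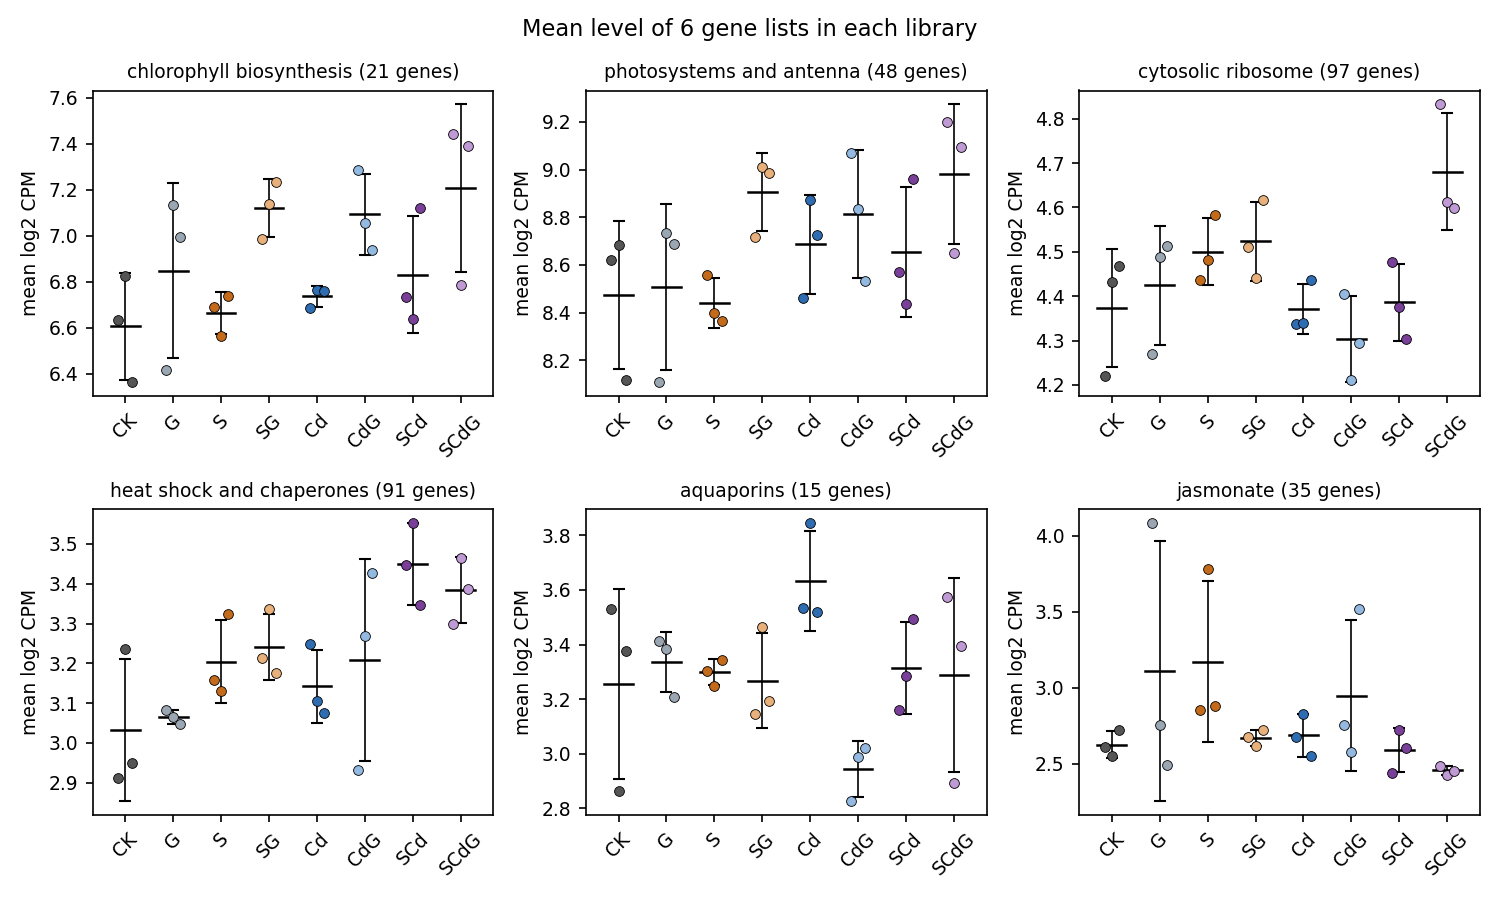
Mean log2 CPM per library of the chlorophyll biosynthesis (21 genes), photosystem (48), ribosome (97), heat shock (91), aquaporin (15) and jasmonate (35) lists in the 8 groups; points are libraries, and marks with bars are means ± SD of 3. Chlorophyll genes average 7.21 in SCdG and 6.61 in CK, and aquaporins 2.95 in CdG and 3.63 in Cd.

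The 3 comparisons of GABA-treated stress groups with CK were added after the data were seen, and ask how far these groups stood from control leaves. In SCdG against CK, MYB29 (Pmo08G023530) fell from 4.83 ± 3.74 to 0.229 ± 0.0527 CPM (log2 difference -4.39 ± 0.63), DREB1E (Pmo05G007990), of a family of cold and drought factors, from 5.37 ± 1.48 to 0.278 ± 0.253 CPM (-4.28 ± 0.59), and IAA1 from 30.3 ± 27.4 to 2.33 ± 0.750 CPM (-3.70 ± 0.64). Folate-biopterin transporter 8 (Pmo01G004470, -3.66 ± 0.47), a second DOG1-like 4 gene (Pmo04G005600, -3.38 ± 0.89) and sugar transport protein 10 (Pmo01G005740, -3.37 ± 0.83) fell too. The Pru ar 1-like allergen gene (Pmo01G010520) stood at 1.16 ± 0.356 CPM against 0 in all 3 CK libraries. Non-specific lipid-transfer protein 3 (Pmo06G025600, 5.29 ± 1.1), glucan endo-1,3-beta-glucosidase (Pmo07G005650, 6.21 ± 1.7), an L-type lectin protein (Pmo08G010080, 4.39 ± 1.1), peroxidase 66 (Pmo02G024640, 3.56 ± 0.89) and the beta-galactosidase Pmo07G018960 (654 ± 513 against 47.4 ± 39.5 CPM, 3.79 ± 0.81) rose. All 12 were separated, as the naming rule required, with edgeR adjusted p from 0.000286 to 0.0324. The glucosidase (4.34 ± 6.74 CPM in SCdG) and the lectin (2.26 ± 3.17 CPM) were carried by SCdG replicate 1, at 12.1 and 5.92 CPM. Without it their log2 differences were 2.96 (0.273) and 1.98 (0.244), and DOG1-like 4 had -2.17 without CK replicate 1 (0.155).

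Of 21 chlorophyll biosynthesis genes 3 rose in SCdG against CK by the gene test and 11 adjusted over the list alone, and 19 had a positive difference. Protochlorophyllide reductase rose from 136 ± 97.7 to 765 ± 313 CPM (2.49 ± 0.46, edgeR adjusted p = 0.00304) and magnesium-protoporphyrin IX methyltransferase from 64.6 ± 22 to 179 ± 41.2 CPM (1.47 ± 0.28, 0.00373), and glutamyl-tRNA reductase 2 (Pmo08G006860) rose by 0.69 ± 0.20 (0.0369). Of 48 photosystem genes 7 passed as higher and 0 as lower, and adjusted over the list alone 15 and 1. They include CP24 (1.28 ± 0.31, 0.0144), LHCII type 1 (1.00 ± 0.25, 0.0179, not separated) and PSB27-H1 (1.56 ± 0.39, 0.018). Of 97 ribosome genes 15 passed, all higher, and 24 adjusted over the list alone, among them RPL27a-3 (Pmo01G021300, 0.62 ± 0.14, 0.00964), RPL4 (Pmo01G006340, 0.76 ± 0.17, 0.0108) and RPS3-3 (Pmo07G018310, 0.85 ± 0.21, 0.0155). The morning clock factors REVEILLE 8 (-1.74, 0.000104) and LHY (-1.50, 0.00177) fell and the evening gene ELF4-LIKE 3 rose (1.79, 0.0066); these 3 were named after their values were seen, and the clock score was 4.82 ± 1.43 in SCdG and -3.73 ± 2.50 in CK. Camera adjusted p was 0.000208 for chlorophyll, 0.000141 for photosystem and 3.4e-10 for ribosome genes, each 0.880 with an estimated correlation.

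EdgeR called 1761 genes in SCdG against CK (849 higher, 912 lower, 814 at least 2-fold), and 4741 had an unadjusted p under 0.05. The count was 718 without CK replicate 1, 2552 without CK replicate 2 (1346 of them higher), 540 without CK replicate 3, 833 without SCdG replicate 1, 2219 without SCdG replicate 2 and 820 without SCdG replicate 3. With only the 6 compared libraries in the model edgeR called 0, and with all libraries DESeq2 called 2829 and limma 1696. Of 24 named genes past the test, MYB29, DREB1E, REVEILLE 8 and 9 more kept it without CK replicate 1, 21 without CK replicate 2, 11 without CK replicate 3, 12 without SCdG replicate 1, 24 without SCdG replicate 2 and 17 without SCdG replicate 3. In SG against CK, photosystem (39 of 48), chlorophyll (20 of 21) and ribosome genes (74 of 97) lay higher (camera adjusted p = 1.96e-06, 9.92e-06 and 0.00894, each 0.880 with an estimated correlation; 2 chlorophyll genes adjusted over the list alone). In CdG against CK, photosystem (39 of 48) and chlorophyll genes (21 of 21) did (2.42e-05 and 1.42e-07, each 0.880 with an estimated correlation; 8 chlorophyll genes adjusted over the list alone), and MCA2 stood at 0.398 ± 0.132 against 0 CPM (edgeR adjusted p = 0.0353), a call not made with a replicate block, counts divided by 4 or only the compared groups. With edgeR 0 genes passed in SG against CK (2693 at an unadjusted p under 0.05; DESeq2 455, limma 0) and 1 in CdG against CK (1942; DESeq2 117, limma 0). Without CK replicate 2 these counts were 1032 and 535; without CdG replicate 3 the latter was 2, and without any other library it was 0.

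Averages over pairs of groups that differ in 1 treatment, also added after the data were seen, ask for effects shared by the backgrounds. Over 4 pairs with and without alkali-salt the genes that fell were IAA1 (19 ± 14.8 to 5.30 ± 3.83 CPM over 12 libraries each, log2 difference -1.99 ± 0.30, edgeR adjusted p = 0.000832), a polygalacturonase-like gene (Pmo06G017810, -1.56 ± 0.22), phytoene dehydrogenase (Pmo06G003580), an early step of carotenoid synthesis (-1.25 ± 0.16), and REVEILLE 8 (-0.78 ± 0.09). Thioredoxin-like 1-2 (Pmo05G017390, 1.68 ± 0.30) and SNF1 subunit gamma 1 (1.56 ± 0.30) rose. Over 4 pairs with and without cadmium the genes that rose were MIEL1 (25.8 ± 36.5 to 94.4 ± 78.4 CPM, 2.1 ± 0.31), beta-galactosidase Pmo07G018960 (2.08 ± 0.38), a universal stress protein (Pmo08G023640, 1.78 ± 0.41) and dnaJ 11 (1.51 ± 0.29), and APS reductase 3 (348 ± 160 to 152 ± 76.1 CPM, -1.29 ± 0.21) and MYB29 (-1.60 ± 0.28) fell. These genes were named after their values were seen, and the clock score was higher in the treated group of every pair. Each gene kept its call without any single library. All moved the same way in 4 of 4 pairs, but this was a condition of their choice except for REVEILLE 8. Genes with the smallest p for alkali-salt were chosen without it. Of these, DETOXIFICATION 21 (Pmo07G002610), a LON peptidase gene (Pmo05G017680) and CONSTANS-LIKE 1 (Pmo03G020220) were lower on average but higher in 1 of 4 pairs. Pmo04G003970 was higher in 3 of 4, and REVEILLE 8 and Pmo03G001770 were lower in all 4. For cadmium such genes moved 1 way in all 4. Heat shock genes (10 of 91 past the test, none lower) and ribosome genes (9 of 97, none lower) lay higher as lists with alkali-salt (camera adjusted p = 0.0239 and 1.37e-11), and with cadmium photosystem (2 of 48), chlorophyll (2 of 21) and heat shock genes (6 higher, 2 lower) lay higher (camera adjusted p = 0.000506, 0.0395 and 0.0223). With an estimated correlation these were 0.785, 0.785, 0.814, 0.814 and 0.785. When adjusted over the list alone 15 heat shock genes were higher and 3 lower and 26 ribosome genes higher with alkali-salt, and 2 photosystem, 2 chlorophyll and 9 heat shock genes were higher (2 heat shock genes lower) with cadmium.

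EdgeR called 1152 genes for alkali-salt (514 higher, 638 lower; 763 to 1947 with a library left out) and 912 for cadmium (543 higher, 369 lower; 619 to 1667). With limma on log2(FPKM + 1) both balances turned, to 612 higher and 473 lower for alkali-salt and 407 and 472 for cadmium, as they did on log2(FPKM + 0.1). For alkali-salt edgeR also had more higher than lower genes without CK replicate 2 (1023 and 924) and among those at least 2-fold (106 and 54). The count for alkali-salt was 763 without CK replicate 1 and 1947 without CK replicate 2, and that for cadmium 619 without CK replicate 3 and 1667 without CK replicate 2. GABA over the 3 stress pairs left chlorophyll (20 of 21), photosystem (43 of 48), carbon fixation (10 of 12), scavenging (24 of 33) and ribosome genes (86 of 97) higher and clock genes lower (13 of 19 negative). By camera, adjusted p was 1.5e-11, 6.63e-13, 0.00725, 0.0152, 4.84e-08 and 0.0466, all 0.785 with an estimated correlation. Adjusted over the list alone 14 chlorophyll, 15 photosystem and 1 ribosome gene were higher and 6 clock genes lower. With edgeR 0 genes passed for GABA over 3 pairs (smallest adjusted p 0.0571, with 2593 at an unadjusted p under 0.05). Without SCdG replicate 2 edgeR called 107. It called 1 without S replicate 2, SCd replicate 1 or 3, SG replicate 1 or SCdG replicate 1. DESeq2 called 422 and limma 2. With only the 6 compared groups in the model edgeR called 98 (57 higher, 41 lower), and on counts divided by 4 it called 1. Over 4 pairs 0 passed as well (0.129; 2736; DESeq2 311, limma 3), and 294 did without CK replicate 2, 65 without SCdG replicate 2, 2 without G replicate 1 and 1 without SCd replicate 3. There chlorophyll (21 of 21), photosystem, carbon fixation and ribosome genes were higher and WRKY factors lower (camera adjusted p = 1.14e-11, 4.82e-10, 0.0127, 1.15e-06 and 0.0285, and 0.785 to 0.811 with an estimated correlation). When adjusted over the list alone 16 chlorophyll genes, 15 photosystem genes and 1 ribosome gene were higher there and 1 photosystem gene lower.

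Cadmium over the 2 pairs without GABA, also chosen later, gave 159 genes (90 higher, 69 lower; 4 with only the compared groups in the model, 5 without CK replicate 3 and 973 without CK replicate 2). Without S replicate 1, 2 or 3 more of the called genes were lower than higher (39 of 72, 30 of 55 and 8 of 14), as without CK replicate 3 (3 of 5). Photosystem genes lay higher there (38 of 48) and ribosome genes lower (77 of 97; camera adjusted p = 0.00725 and 0.00384, and 0.892 and 0.850 with an estimated correlation). An exact permutation test of list means over the 3 stress pairs with and without GABA (8000 arrangements, two-sided, 35 lists) gave the chlorophyll list a difference of 0.40 (log2 CPM, p = 0.00225, adjusted p = 0.07), the scavenging list 0.11 (0.0055, 0.07), ion transport -0.11 (0.006, 0.07) and the photosystem list 0.31 (0.0152, 0.089). Chlorophyll breakdown genes had -0.20 (0.0095, adjusted p = 0.0735) and pathogenesis-related genes -0.24 (0.0105, 0.0735), so no list passed this test after adjustment.

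The clock list was kept as a measure of harvest time, and its first principal component over the 24 libraries held 44.8% of its variance. The score averaged -3.73 ± 2.50 in CK, -2.25 ± 2.04 in G, -1.57 ± 0.90 in S, -1.18 ± 0.46 in Cd, 0.03 ± 1.03 in CdG, 1.51 ± 0.83 in SG, 2.36 ± 1.28 in SCd and 4.82 ± 1.43 in SCdG. CK replicate 2 (-0.853) stood apart from CK replicates 1 (-4.92) and 3 (-5.41). Over 24 libraries, deviations from group means of the signed mean of the genes called in SCdG against CK followed those of the score (r = 0.904, permutation p = 0.00013; rho = 0.866, p = 0.00031; 0.845 without the 2 farthest libraries; adjusted p = 0.00078 over 6 relations). This relation uses the groups that chose the genes; over the other 18 libraries r of such deviations was 0.818.

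**Figure D4:**
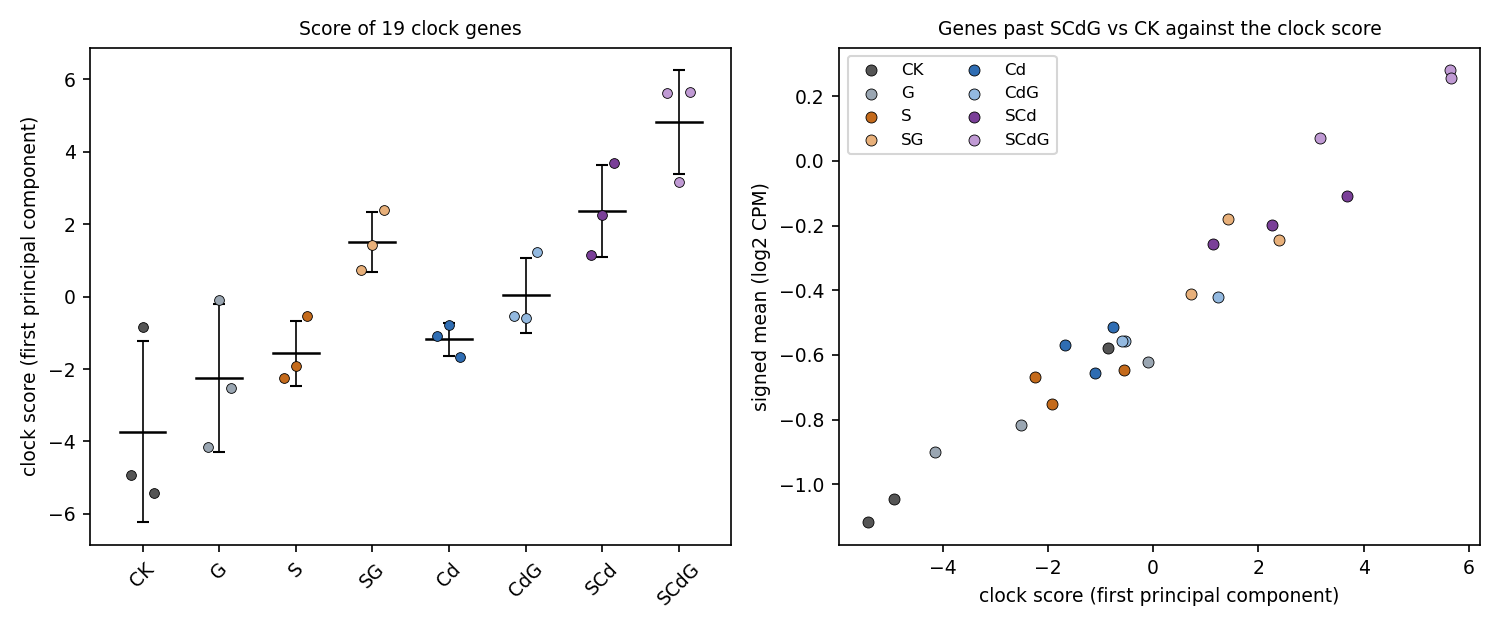
Left, clock score (first principal component of 19 clock genes, no unit) of each library by group, with mean ± SD of 3; right, signed mean log2 CPM of the genes past the test in SCdG against CK, plotted against the score in 24 libraries. The score runs from -5.41 in a CK library to 5.66 in an SCdG library.

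GABA metabolism genes, which make, break down or carry GABA inside the plant, held 10 tested members, 8 of them at 1 CPM or more, and 0 passed the edgeR test in any of the 12 pairwise comparisons. Among those 8, log2 differences ran from -0.37 to 0.28 in Cd against CK, -0.32 to 0.53 in SCd against CK and -0.90 to 0.50 in SCdG against SCd. The smallest edgeR adjusted p was 0.163, for a GABA transporter (Pmo08G019930) in SCdG against CK, where the 8 ran from -1.14 to 0.35. No gene described as a phytochelatin synthase was among those tested. Among metallothionein and nicotianamine synthase genes, which bind metals or make metal chelators, 5 were tested, 4 of them at 1 CPM or more, and 0 passed. Those 4 ran from -1.0 to 0.42 in Cd against CK (smallest edgeR adjusted p 0.746), with Pmo06G022350 at -1.0 (-0.56 without CK replicate 3), and a nicotianamine synthase-like gene (Pmo06G027340) had 1.24 in SCd against S (0.257).

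Over the 9 planned pairwise comparisons camera made 30 calls in 14 of the 35 lists. No call was made with an estimated correlation (smallest adjusted p 0.842) or by fry (0.275). The other 21 lists had none: MYB factors (smallest camera adjusted p 0.0798), class III peroxidases (0.083), ethylene (0.126), cell division (0.141), sulfur assimilation (0.146), auxin, pathogenesis-related and NAC genes (0.167 each), flavonoid (0.197), chlorophyll breakdown and senescence (0.199), and osmolytes (0.203). Nor had glutathione and phytochelatin (0.228), seed storage (0.228), nitrogen assimilation (0.286), ion transport (0.372), root (0.372), abscisic acid (0.378), starch and sucrose (0.380), iron (0.381), GABA metabolism (0.429) and metal transport genes (0.665).

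Responses to single and combined stress were compared over 19435 genes that share the CK libraries. The correlation of log2 differences across genes, which are not independent replicates, was 0.523 for S and Cd, 0.492 for S and SCd and 0.563 for Cd and SCd, where 20 simulations of unchanged groups against the same controls averaged 0.500, 0.505 and 0.502. Covariances were 0.221, 0.233 and 0.251 beside simulated values of 0.162, 0.164 and 0.164. Of the genes called in SCd against CK, 72 of 79 higher and 108 of 113 lower ones were also called the same way in SCdG against CK and 0 the opposite way by edgeR. That pair shares the 3 CK libraries as well, and had r = 0.684 (simulated 0.504). SCd against CK and SCd against S share the SCd libraries in place of CK and had r = 0.541 (simulated 0.501).

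Distance to control asks whether GABA moved stressed leaves toward control. Genes were picked in 2 replicate numbers and measured in the held-out one, which gave genes in 1 of 9 cases, SCd with replicate 2 held out (109 genes). Their median signed log2 difference from the held-out CK library was 0.452 in the SCd library and 0.434, 0.761 and 0.545 in the 3 SCdG libraries (mean 0.580). These values carry no test, and the held-out control is CK replicate 2, the library that stands apart.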

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

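Chosen after the result was seen were the clock covariate fits of gene counts, the test of a few members with large differences, the bound on what the clock covariate left of the GABA by alkali-salt genes, and the requirement, in the tests of the GABA by alkali-salt genes, that a bound be met by more than its spread.

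A test of the difference between responses picked out 3 results. Pmo01G015990 and nucleoredoxin 3 were the 2 genes past the interaction of alkali-salt and cadmium, and 3 of 25 arrangements of the libraries gave as many genes or more, so chance is not excluded. The highest other arrangement gave 769 genes beside the real 2, which points to a structure of the samples that was not tested. MIEL1, beta galactosidase 1 and 9 others were the 11 genes past the interaction of GABA and alkali-salt. Only the real arrangement of 25 gave as many (highest other 0), which argues against chance as far as 25 arrangements can. It does not exclude it, and 0 genes passed without any G library, any S library or SG replicate 2. Pmo01G015990 was the 1 gene past the interaction of GABA and cadmium, and 4 of 25 arrangements gave as many (highest other 1), so chance is not excluded.

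The first pattern weighed is the 1761 genes past the test in SCdG against CK, such as MYB29, DREB1E and protochlorophyllide reductase. Low counts are argued against, since 2.44% of the called genes had a mean under 1 CPM beside 18.6% of those tested. The state of the daily clock may share in the pattern: over 18 libraries of the other 6 groups, deviations of the genes outside the clock list followed the clock score (r = 0.818, permutation p = 0.0023; rho = 0.783, p = 0.0031; 0.700 without the 2 farthest libraries; adjusted p = 0.0069 over 6 relations), while total count did not (r = -0.146, p = 0.644). With the score as covariate 0 of the genes passed in edgeR, where the median log2 difference fell from 0.94 to 0.25 and its SE rose from 0.22 to 0.40, so the calls ended through both. Time of harvest and an effect of the treatments on the clock stay open, because the score and the groups overlap.

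The second pattern is the chlorophyll biosynthesis list, higher with GABA over the 3 stress pairs. A few members with large differences as the source are argued against. The median log2 difference of the members was 0.866 of their mean (bootstrap SD 0.169), and 20 of 21 were positive. Each member counts equally there whatever its CPM, so the part of abundant genes was not tested. The clock may share in this pattern too: with the score as covariate the difference fell from 0.40 ± 0.11 to 0.13 ± 0.10 (log2 CPM ± SE), keeping 32.6%. The photosystem list kept 30.6%, the ribosome list 41.6% and the scavenging list 96.9%. An effect of GABA on chlorophyll genes stays open as a biological explanation that these data do not separate from the clock.

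The third pattern is the 11 genes of the GABA by alkali-salt interaction. Without CK replicate 2 their median log2 interaction kept 76.1% of its size, the lowest of 12 libraries left out (SD 9.07), which lies within the bound of 25% by less than that spread, so a single library as the source could not be excluded. The clock as their whole source is argued against: with the score as covariate the median kept 86.9% (2.60 to 2.26, SE 0.40 before and 0.38 after, which is 14.5% of the median), while the same covariate took the SCdG against CK genes from 0.94 to 0.25. In that fit 0 of the 11 passed in edgeR; they had stood at adjusted p = 0.0498, and the calls ended with this small fall and without a larger SE. A share of the clock stays open. Deviations of these genes over the 12 libraries of the other 4 groups had r = -0.186 with the clock score (permutation p = 0.446), nearer to the bound of 0.2 than the spread of permuted values (0.224), which excludes no share. A biological explanation, a response to GABA that differs under alkali-salt, stays open and untested.

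With the clock score as covariate, edgeR called 0 genes in SCd against CK (192 without it; median log2 difference 1.13 to 0.55, SE 0.23 to 0.32), 73 in SCd against S (334, of which 32 kept; 1.08 to 0.92, SE 0.23 to 0.28), 0 for alkali-salt over 4 pairs (1152; 0.50 to 0.21, SE 0.11 to 0.18), 39 for cadmium over 4 pairs (912, of which 14 kept; 0.53 to 0.35, SE 0.12 to 0.18) and 0 for cadmium over 2 pairs (159; 0.91 to 0.73, SE 0.19 to 0.25). The score itself was related to 695 genes in that model. In SCd against S and for cadmium over 2 pairs the median difference stayed near its size while its error grew, so the calls lost there are no evidence for the clock.

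Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Splits with at least the real count, then the real count and the highest other, were 1 for SCd against CK (192, 1), 1 for SCd against S (334, 0), 1 for SCdG against CK (1761, 52), 3 for Cd against CK (1, 10), 2 for CdG against Cd (1, 2) and 4 for CdG against CK (1, 30). Where the real count was 0, all 10 splits reach it by construction: the highest other was 1 for S against CK, 44 for G against CK, 0 for SG against S, 638 for SCdG against SCd, 0 for SCd against Cd and 30 for SG against CK. The 638 genes came from SCdG replicates 1 and 3 with SCd replicate 3, set against SCdG replicate 2 with SCd replicates 1 and 2. That split follows the clock score (5.64, 5.66 and 3.69 against 3.17, 1.14 and 2.25). It also follows the first principal component over all genes (83.1, 71.7 and 38.4 against 8.37, -10.1 and 3.86). What sets these libraries apart was not tested. Genes at an unadjusted p under 0.05 were many in other splits as well. Their highest other count exceeded the real one for S against CK (1756, real 1383), Cd against CK (1916, 1267) and G against CK (2360, 1458). So it did for SCdG against SCd (3870, 1693) and CdG against CK (2425, 1942). In the other pairwise comparisons it stayed below the real count, as in SCd against CK (2334, 2752).

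Of 25 arrangements, only the real one gave as many genes for alkali-salt over 4 pairs (1152, highest other 1), cadmium over 4 pairs (912, highest other 0) and cadmium over 2 pairs (159, highest other 1). This argues against chance for these counts as far as 25 arrangements can. For counts of 0, all 25 reach it by construction, so nothing about chance follows: the highest other was 1 for GABA over 4 pairs, 3 for GABA over 3 pairs and 2 for the interaction of GABA with the combined stress.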

How the results depend on the processing

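Counts divided by 4, fry, the added comparisons and camera with a library left out were chosen after the data were seen. If 1 fragment gave 4 counts, totals are 13 to 17 M fragments per library, so genes of a few fragments, such as MCA2 at 0.365 CPM in Cd, lie near the lower limit of what this depth measures. For the changes given here the cause was not tested. Fits of the compared groups alone rest on fewer libraries and so on a less certain spread. Counts moved both ways in those fits, and SCd against S rose from 334 to 465 genes. Whether fewer libraries account for the changes was not tested. Of 2078 combinations of the 128 named genes and a setting, 1694 kept direction and side of the threshold, 364 kept direction and no longer passed, 20 newly passed and 0 changed direction. No filter left every count within 1.5 times its value.

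DESeq2 called 55 genes in S against CK, 45 in Cd against CK, 927 in SCd against CK, 38 in G against CK, 192 in SG against S, 66 in CdG against Cd, 69 in SCdG against SCd, 858 in SCd against S, 203 in SCd against Cd, 455 in SG against CK, 117 in CdG against CK and 2829 in SCdG against CK. It called 113 for the interaction of alkali-salt and cadmium, 241, 33 and 17 for those of GABA with alkali-salt, cadmium and both, 2003 for alkali-salt and 1648 for cadmium over 4 pairs, 737 for cadmium over 2 pairs, and 311 and 422 for GABA over 4 and 3 pairs. Limma on log2(FPKM + 1) called 2 in S against CK, 0 in Cd against CK, 315 in SCd against CK, 6 in SCd against Cd, 0 in CdG against CK, 0 for GABA by alkali-salt, and 3 and 2 for GABA over 4 and 3 pairs. On log2(FPKM + 0.1) it called 1 in S against CK, 0 in Cd against CK, 313 in SCd against CK, 6 in SCd against Cd, 0 for GABA by alkali-salt, and 3 and 2 for GABA over 4 and 3 pairs.

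With only the compared groups in the model edgeR called 0 in Cd against CK, SCd against CK, CdG against Cd, CdG against CK and SCdG against CK, 2 in SG against S, 0 for the interactions of alkali-salt with cadmium and with GABA, 2 for GABA by cadmium, 98 for GABA over 3 pairs and 4 for cadmium over 2 pairs. Averages over 4 pairs use every group, so this setting gives them no further value. Counts divided by 4 gave 0 in Cd against CK and CdG against CK, and 1 for GABA over 3 pairs; RLE scaling gave 7 in SCd against Cd. At a log2 difference of at least 1 there were 114 genes in SCd against CK, 190 in SCd against S, 814 in SCdG against CK, 160 for alkali-salt and 134 for cadmium over 4 pairs, and 72 for cadmium over 2 pairs.

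Sample numbers did not pair the libraries: deviations of same-numbered libraries had a mean r of -0.0047 beside 0.0024 for others. A replicate block gave 0 genes in Cd against CK, 3 in SG against S, 1 in SG against CK, 6 for alkali-salt by cadmium and 6 for GABA by alkali-salt, 5 of them among the 11. In CdG against CK it gave 1 gene, as did limma on log2(FPKM + 0.1), and in each the gene was lower in CdG and was not MCA2.

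With a library left out the lowest and highest counts were 0 and 51 (S against CK, without CK replicate 2), 0 and 202 (Cd against CK, CK 2), 2 and 1355 (SCd against CK, CK 3 and CK 2), 0 and 6 (G against CK, CK 2), 0 and 1 (SG against S, SG 1), 0 and 2 (CdG against Cd, CdG 3), 0 and 1 (SCdG against SCd, SCdG 1), 52 and 105 (SCd against S, SCd 1 and S 2) and 0 and 1 (SCd against Cd, Cd 1 or Cd 3). They were 0 and 1032 (SG against CK, CK 2), 0 and 535 (CdG against CK, CK 2) and 540 and 2552 (SCdG against CK, CK 3 and CK 2). For interactions they were 0 and 4 (alkali-salt by cadmium, S 3), 0 and 64 (GABA by alkali-salt, CK 3), 0 and 1 (GABA by cadmium, 0 without Cd 1) and 0 and 5 (GABA by the combined stress, CK 2). For averages they were 763 and 1947 (alkali-salt, CK 1 and CK 2), 619 and 1667 (cadmium, CK 3 and CK 2), 0 and 294 (GABA over 4 pairs, CK 2), 0 and 107 (GABA over 3 pairs, SCdG 2) and 5 and 973 (cadmium over 2 pairs, CK 3 and CK 2).

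Camera calls numbered 30 in the 9 pairwise comparisons, 8 in the added ones, 14 in the interactions and 18 in the averages. They were 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 0 with fry, 32, 8, 14 and 18 with RLE scaling, and 30, 8, 15 and 18 with a replicate block; with a library left out the pairwise calls ranged from 21 (CK 3) to 35 (Cd 3). The excess covariance of the S and SCd responses fell from 0.0687 to 0.0452 among genes of at least 1 CPM. Distance to control was 0.452 in SCd and 0.580 in SCdG, and 0.459 and 0.600 with RLE scaling. At a log2 difference of at least 1 it was the same, since the 109 genes were the same; the other 8 held-out cases had 0 genes by edgeR and so no value.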

Other observations

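Every test of this part was chosen after the result was seen. Pathway names of the deposited table were tested among the genes past the edgeR test (one-sided Fisher tests, 120 pathways, background 4757 genes). Genes higher in SCdG than in CK held 26 of 175 members of protein processing in the endoplasmic reticulum, where secreted and membrane proteins fold (9.12 by chance, Fisher adjusted p = 5.1e-05), 35 of 275 ribosome members (14.3, 5.1e-05), 6 of 16 antenna proteins (0.834, 0.00389) and 12 of 69 phagosome members (3.60, 0.00572). Lower genes held 28 of 325 members of hormone signal transduction (13.9, 0.0138) and 9 of 46 of the circadian rhythm (1.96, 0.0131). With alkali-salt over 4 pairs, endoplasmic reticulum processing (18 members, 5.33 by chance, 0.000542) and ribosome members (21, 8.38, 0.00434) were over-represented among higher genes. Circadian rhythm (10, 1.21, 2.4e-05), hormone signalling (21, 8.54, 0.00536) and motor proteins (8 of 81, 2.13, 0.0468) were so among lower ones. Cadmium over 4 pairs gave only the circadian rhythm among lower genes (6, 0.716, 0.00793). SCd against CK and SCd against S gave 0 of 120 pathways (smallest adjusted p 0.103 and 0.378). The Fisher test takes genes as independent, which members of a pathway are not.

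Several lists had members past the edgeR test in SCdG against CK without a camera call. Heat shock and chaperone genes had 11 higher and 1 lower of 91 (camera adjusted p = 0.124), ethylene genes 3 and 9 of 74, ion transport genes 6 and 9 of 97, and sulfur assimilation genes 0 and 3 of 25 (2 and 8 adjusted over the list alone, camera adjusted p = 0.0629). Over all 19435 genes 849 were higher and 912 lower, and the counts of these lists were not tested against that share. The clock score was 4.82 in SCdG and -3.73 in CK.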
